A study of Mus musculus with 6 samples.

How the data were processed

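Total RNA of sorted mouse bone marrow cells was amplified, labelled with biotin and hybridised to whole-transcript mouse gene arrays, 1 array per bone marrow sample, per the labels' protocols. The labels name 6 arrays as separate biological replicates, 3 in the group labelled Zeb2-KO (Zeb2 fl/fl Mx1-Cre mice) and 3 in the wild-type group (WT). Groups were taken from the titles and genotypes in the labels. The deposited table holds 1 intensity per probe set and array, and the submitters' processing notes name RMA, a method that corrects background, normalizes and summarises probes into probe sets. The RMA version, the software and any later scaling are not given in the sources used here. RMA usually gives log2 values, but the deposited intensity values lie on a linear scale, as judged from their range, so log2 was taken before any test, as had been foreseen. Median intensities per array were 98.7, 99.2 and 96.8 in the arrays labelled Zeb2-KO replicates 1 to 3 and 97.9, 98.9 and 94.3 in WT replicates 1 to 3. The interquartile ranges differed between arrays, so the deposited values do not share 1 distribution. Array values carry no read depth, and their precision is limited by the 3 arrays in each group.

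Of the 20220 probe sets in the table, 5610 have identifiers below the first annotated one. They carry no gene in the annotation used and were treated as a block of control probe sets and left out, a choice made after the table was seen because the planned rule looked for control names that the table does not use. The other 14610 probe sets were tested. Of these, 11229 carry 1 gene symbol, 766 carry several and 2615 carry none in the platform annotation, and no gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 11184 were found by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes. The single symbols come to 10366 different genes. Genes without a single-symbol probe set, among them Epor, Csf1r, Csf3r, Gata1 and Cdh1, were not analysed here.

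The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, 4 residual degrees of freedom and 6.87 prior degrees of freedom), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A descriptive count used an unadjusted p under 0.01 and a change of at least 1.5-fold. Differences are log2 values of the arrays labelled Zeb2-KO minus WT, with limma's standard error (SE), and group values are mean ± SD of 3 arrays. For 21 gene lists fixed before the data were examined, 1 probe set per gene was used (that with the highest mean over all arrays). Of their 585 symbols, 379 were measured. The 20 lists with at least 8 measured members were tested with camera (limma) at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. The remaining list, sex-linked genes, was too short to test. Counts "adjusted over the list alone" use only the members of 1 list.

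The named genes follow a rule fixed before the data were examined. They are Zeb2, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold and without overlap between groups, up to 4 members of each list with the smallest p, and 31 fixed genes, of which 20 were measured. Only Fap passed, so each direction was filled up to 12 in order of unadjusted p, among probe sets at or above the median mean (log2 6.63) and changed at least 1.5-fold. Probe sets outside the rule that are named below were chosen after their values were seen.

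Alternatives fixed in advance were a filter on dim probe sets, quantile normalization, centring of arrays, a trended or robust variance prior, array weights, the replicate number as a block, 1 or all probe sets per gene, the other list tests, and leaving out each array in turn. Alternatives added after seeing the data were the control block included, the interquartile range of each array as a covariate, and the arrays with raised Y-linked signal left out together. The procedure was tested on simulated data, 10 sets of 14610 probe sets with 200 changed and with means and residual spreads of the real arrays. It recovered 73.9% of changes of log2 size 2, 89.9% of size 3 and 97.1% of size 4 in these simulated sets, with a mean of 10 false calls per set. A simulated shift of 0.75 in the megakaryocyte and platelet list was called in 10 of 10 sets with the preset correlation and in 3 of 10 with an estimated correlation. The simulation draws probe sets independently, so the genes of a list are not correlated in it. In the lists called in the real arrays the estimated correlation ran from 0.1069 (erythroid) to 0.5443 (cell cycle). It was 0.2465 in the megakaryocyte and platelet list. The simulated list calls therefore do not test the preset correlation, nor give the power of either list test in the real arrays. The 200 planted changes of the simulation make the adjusted threshold easier to pass than in the real arrays, which gave 2 calls. The recovered shares therefore do not give the power in the real arrays. There Ppbp at 3.28 and a probe set of Adgrl2 at 3.84 (log2) did not pass (limma adjusted p = 0.333 and 0.286). Figures were drawn with matplotlib 3.10.9.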

Results

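Expression was measured in LKS-Slam cells, bone marrow cells that lack lineage markers, carry Kit and Sca-1 and are sorted further on SLAM surface markers, a gate highly enriched for hematopoietic stem cells. The mice labelled Zeb2-KO carried floxed Zeb2 alleles and Mx1-Cre, a recombinase switched on by interferon. They and WT mice received polyinosinic-polycytidylic acid (pIC), an interferon inducer, at 6 weeks of age, and cells were taken 8 weeks later, at 14 weeks. Each group had 3 arrays, 1 per bone marrow sample. The comparison asks which transcripts of stem cell-enriched marrow differ after induced deletion of Zeb2, a zinc-finger repressor known for its part in epithelial-mesenchymal transition.

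Zeb2 itself was higher, not lower, in the arrays labelled Zeb2-KO, at a log2 intensity of 8.63 ± 0.73 against 7.14 ± 0.49 in WT (SD, n = 3), a difference of 1.48 (SE 0.40) or 2.80-fold that did not pass the test (limma adjusted p = 0.581). Fap, the fibroblast activation protein, a serine protease of activated stromal cells, rose 9.55-fold. Genes of megakaryocytes and platelets, led by Ppbp (9.73-fold) and Pf4 (4.64-fold), and of erythroid cells, led by Car2 (3.30-fold), lay higher as lists. Genes of B cells, with Ms4a1 at -2.06 (log2), and of monocytes and dendritic cells, with Cd74 at -0.98, lay lower as lists. The list calls held only with the preset correlation between genes, and Fap and 1 unnamed probe set were the only single calls.

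The Zeb2 values were 7.79, 9.13 and 8.96 in the arrays labelled Zeb2-KO and 6.58, 7.51 and 7.34 in WT, without overlap. They come from 1 probe set (10482448). The labels do not say which part of the gene was removed, and a probe set lying outside that part would not check the deletion. Zeb2os, the antisense gene beside Zeb2, stood at 6.71 ± 0.45 against 5.67 ± 0.14, a difference of 1.04 (adjusted p = 0.606). Because Zeb2 runs against the label, every direction below is that of the arrays labelled Zeb2-KO against WT, and it rests on the labels alone. With the interquartile range of each array as a covariate the Zeb2 difference was 0.77 (SE 0.30), and with array weights, for which limma reported no convergence, it was 1.67 and passed (adjusted p = 0.0181).

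Of 14610 probe sets tested, 2 passed an adjusted p of 0.05, both higher. Fap (probe set 10483081) stood at 8.71 ± 0.13 against 5.46 ± 0.26 (SD, n = 3), a difference of 3.26 (SE 0.28, adjusted p = 0.00133). The other, probe set 10470911, has no gene symbol in the annotation used and stood at 8.09 ± 0.15 against 3.55 ± 0.23, a difference of 4.55 (SE 0.28, adjusted p = 8.24e-05). Fap did not pass with the array spread as a covariate (adjusted p = 0.102) or without the 2 arrays with raised Y-linked signal (adjusted p = 0.0713), with differences of 3.08 and 3.18, whereas the unnamed probe set passed in both (adjusted p = 0.0171 and 0.0376). With the replicate number as a block neither passed (adjusted p = 0.129 for Fap and 0.0882 for the unnamed probe set). Below an unadjusted p of 0.05 lay 1025 probe sets, 831 of them higher, and 750 with the array spread as a covariate, 366 higher and 384 lower. That count was 4796 with array weights (2516 higher) and 2595 with the replicate number as a block (1416 higher and 1179 lower). With 1 array left out it ran from 537 without Zeb2-KO replicate 2 to 1643 without Zeb2-KO replicate 1 and 1659 without WT replicate 2. At an unadjusted p under 0.01 and at least 1.5-fold there were 228, or 1.56%, where chance gives 1% at that p. Of these 228, 197 were higher and 31 lower (86.4% higher). With the array spread as a covariate that count was 137, 70 higher and 67 lower, and with array weights it was 1864, 1323 higher and 541 lower. The number past the adjusted threshold was 0 with the replicate number as a block, 1 with the array spread as a covariate and 978 with array weights. It was 5 without Zeb2-KO replicate 1, 3 without replicate 2 of that group, 10 without WT replicate 1, 18 without WT replicate 2 and 9 without WT replicate 3. The descriptive count was 409 with the replicate number as a block, 363 without Zeb2-KO replicate 1, 116 without Zeb2-KO replicate 2 and 573 without WT replicate 2. Values of the groups did not overlap in 1923 probe sets (13.2%), where chance gives 10%.

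**Figure D1:**
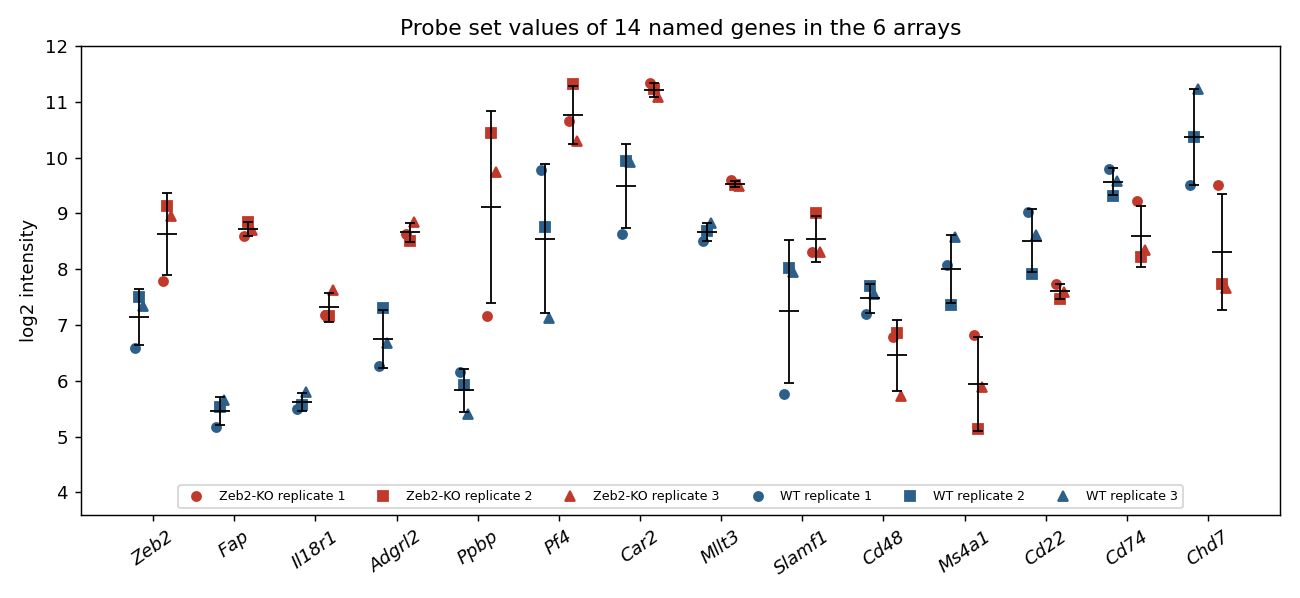
Log2 intensity of 14 named genes in the 6 arrays, WT in blue and arrays labelled Zeb2-KO in red, with a symbol for each replicate number and bars for mean ± SD (n = 3). Zeb2 and Fap lie higher in all 3 arrays labelled Zeb2-KO, Fap at 8.71 against 5.46, and Ms4a1 lies lower in all 3, at 5.95 against 8.01.

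None of the other 23 genes that the naming rule took from the extremes passed the test. On the higher side the smallest p after Fap was that of Aqp9, a water and glycerol channel, with a difference of 2.28 (adjusted p = 0.187). Adgrl2, an adhesion G-protein coupled receptor, lay at 1.91 in the probe set with the smallest p, Timp3, an inhibitor of matrix metalloproteinases, at 2.05 and Eid3 at 2.46. Mindy2 (1.84, and -0.20 in its other probe set), Brox (1.68), Anxa4 (1.61), Snora7a (1.53), Slc17a8 (1.43) and Ubxn7 (1.31) completed that side with Ppbp (3.28). Adgrl2 passed without WT replicate 2 (2.19, adjusted p = 0.0389). On the lower side, Ms4a1, the B cell antigen CD20, and Chd7, a chromatin remodeller, both lay at -2.06, Chd7 in the probe set with the smallest p of 23 that ran from -2.06 to 2.20. Bank1, a B cell scaffold protein, lay at -1.63 and Scd1, the stearoyl-CoA desaturase, at -1.54. The others were Ifi27l2a (-1.21), Mirt1 (-1.20), Ormdl2 (-1.18), Klf7 (-1.18), Snord57 (-1.16), Ccdc167 (-1.14), Sf3b4 (-1.07, and -0.25 in its other probe set) and Arhgap15 (-1.03), and adjusted p lay between 0.187 and 0.602 over these genes.

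The megakaryocyte and platelet list lay higher, with a median difference of 0.75 over 15 measured members, 13 of them higher (camera adjusted p = 2.14e-07, adjusted p = 0.485 with an estimated correlation). No member passed over all probe sets, and 3 passed adjusted over the list alone. These were Ppbp and Pf4, chemokines of platelet granules (differences of 3.28 and 2.21), and Cavin2, a caveolar protein (1.52). Cd9 lay at 1.02 (0.62 without Zeb2-KO replicate 2) and Vwf, the clotting factor carrier, at 0.58. Over all probe sets Ppbp passed without Zeb2-KO replicate 1 (4.26, adjusted p = 0.00807) and Pf4 without WT replicate 1 (2.83, adjusted p = 0.0300). The erythroid list had a median of 0.76, with 9 of 11 members higher (adjusted p = 0.00195, adjusted p = 0.485 with an estimated correlation). It missed the threshold without WT replicate 2 (median 0.50, adjusted p = 0.0506), and its median was 0.47 without Zeb2-KO replicate 2 (adjusted p = 0.00731). Car2, carbonic anhydrase, was the 1 member past the threshold adjusted over the list alone, at 11.22 ± 0.13 against 9.49 ± 0.75. Tfrc, the transferrin receptor, lay at 0.96, Ces2g at 0.85, Aqp1 at 0.76 and Klf1, an erythroid transcription factor, at 0.45.

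The B lymphoid list lay lower, with a median of -0.59 and all 18 measured members lower (camera adjusted p = 3.16e-06, adjusted p = 0.485 with an estimated correlation). Ms4a1, at 5.95 ± 0.85 against 8.01 ± 0.61, alone passed adjusted over the list alone. Cd22 (-0.91), Pou2af1 (-0.87), Cd79b (-0.84) and Ebf1 (-0.61, and -0.23 without Zeb2-KO replicate 2) did not. The monocyte and dendritic cell list had a median of -0.37, with 17 of 19 members lower (adjusted p = 0.000873, adjusted p = 0.524 with an estimated correlation) and none past the threshold adjusted over the list alone. Its members with the smallest p were the antigen presentation genes Cd74 (-0.98), H2-Eb1 (-0.76) and H2-Ab1 (-0.63) and the protease gene Ctss (-1.12). Ctss lay at -0.64 without Zeb2-KO replicate 2, and H2-Ab1 at -1.02 without WT replicate 2. Irf8, a transcription factor of monocytes and dendritic cells, lay at -0.42 (-0.21 without Zeb2-KO replicate 2). Without WT replicate 1 the B lymphoid median was -0.36 and the monocyte median -0.24, and without Zeb2-KO replicate 2 the B lymphoid median was -0.33, all still called. With the array spread as a covariate neither list was called (medians -0.17 and -0.065, adjusted p = 0.102 and 0.384, with 15 of 18 and 11 of 19 members lower), whereas the megakaryocyte and erythroid lists were (medians 0.55 and 0.50, adjusted p = 0.00136 and 0.0160).

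**Figure D2:**
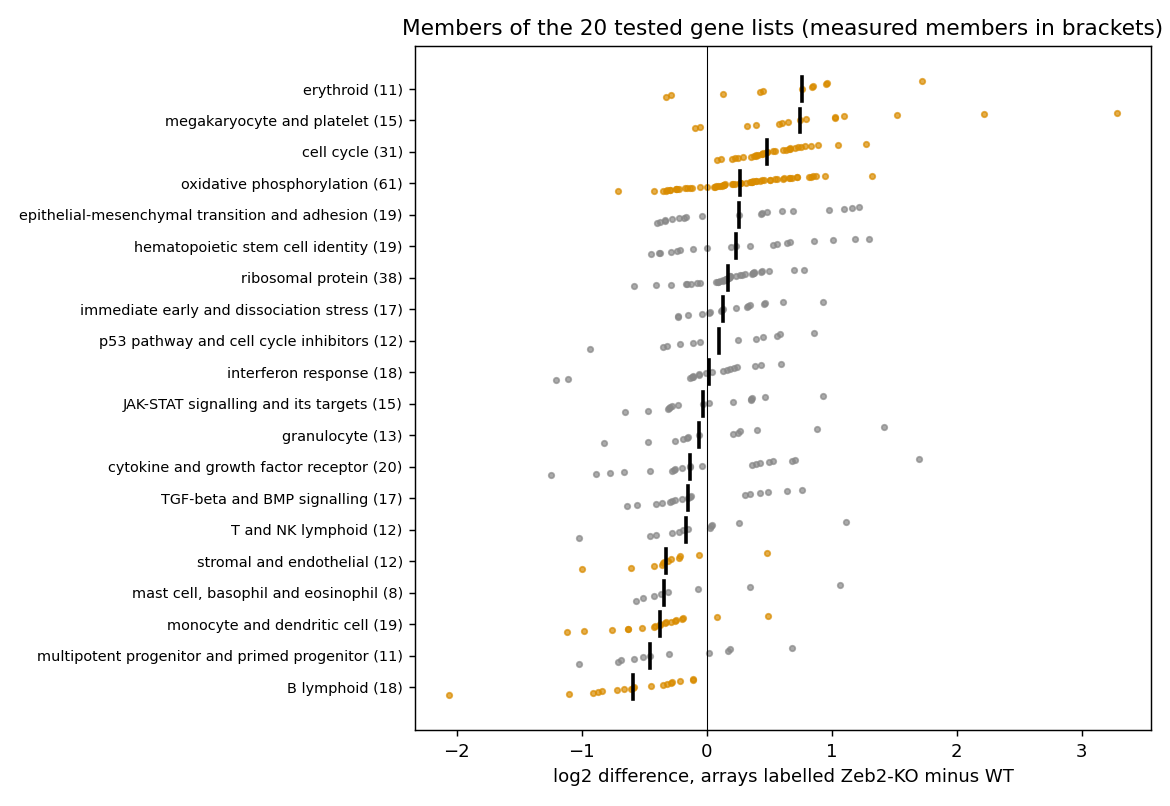
Log2 difference (arrays labelled Zeb2-KO minus WT) of each measured member of the 20 tested lists, as points, with the list median as a black bar, orange for the 7 lists called by camera with its preset correlation. All 18 B lymphoid members lie below 0 and all 31 cell cycle members above it, which become 15 of 18 and 21 of 31 with the array spread as a covariate.

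Genes of the cell cycle lay higher, with a median of 0.48 and all 31 measured members higher (camera adjusted p = 5.2e-07, adjusted p = 0.524 with an estimated correlation). With quantile normalization 29 of 31 lay higher, and with the array spread as a covariate 21 of 31. None of the cell cycle genes passed adjusted over the list alone. Examples are the replication helicase gene Mcm6 (1.05), the spindle motor gene Kif11 (0.89), the mitotic checkpoint gene Bub1 (1.27) and the proliferation marker Mki67 (0.61, and 0.30 without WT replicate 1). Without WT replicate 1 Mcm6 lay at 0.62 and Bub1 at 0.73, and without WT replicate 2 Bub1 lay at 2.03. Genes of oxidative phosphorylation had a median of 0.27, with 45 of 61 higher (adjusted p = 0.0127, adjusted p = 0.805 with an estimated correlation), among them Ndufb8 (1.32) and Cox7b (0.94). The arrays also differed in spread, and the interquartile range of log2 values was 2.11 ± 0.28 in the arrays labelled Zeb2-KO and 1.79 ± 0.22 in WT (SD, n = 3, two-sided exact permutation p = 0.2, with 0.1 the smallest this design can give). With that range as a covariate the cell cycle median was 0.036 (adjusted p = 0.454) and the oxidative phosphorylation median reversed to -0.17 (adjusted p = 0.0160). The oxidative phosphorylation call was also lost with quantile normalization (median 0.057, 32 of 61 higher, adjusted p = 0.416) and without Zeb2-KO replicate 2 (median 0.022, adjusted p = 0.811), WT replicate 1 (0.17, adjusted p = 0.246) or WT replicate 3 (0.20, adjusted p = 0.0544), while the median was 0.43 without Zeb2-KO replicate 1 and 0.42 without WT replicate 2. Ribosomal protein genes had a median of 0.17, with 30 of 38 higher, and were not called (adjusted p = 0.0845). They were called without Zeb2-KO replicate 1 (0.30, adjusted p = 0.0103) and without WT replicate 2 (0.31, adjusted p = 0.0254). Their median was 0.056 without Zeb2-KO replicate 2, 0.033 without WT replicate 1, 0.024 with quantile normalization and -0.14 with the array spread as a covariate, none called.

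**Figure D3:**
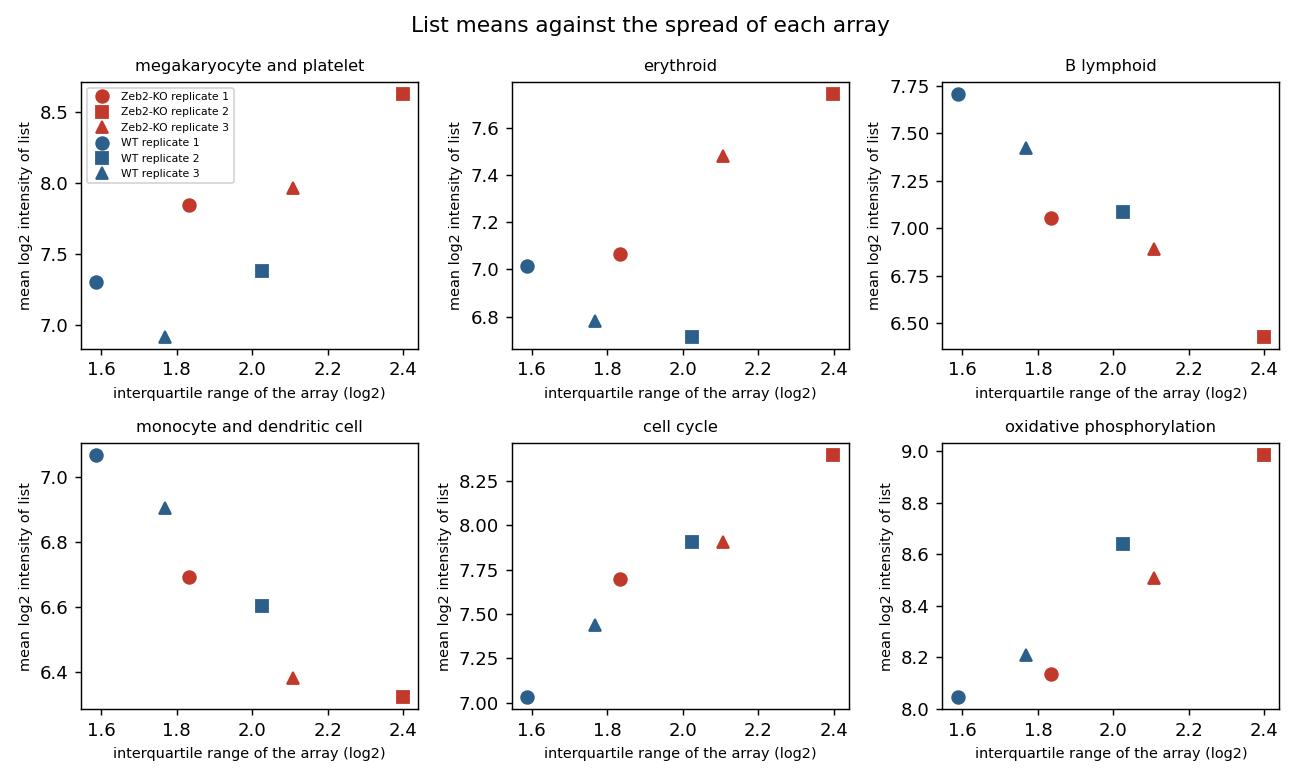
Mean log2 intensity of 6 gene lists (y axis) against the interquartile range of log2 values of each array (x axis), WT in blue and arrays labelled Zeb2-KO in red, 1 point per array. Cell cycle means run from 7.03 in WT replicate 1, the array with the narrowest range (1.59), to 8.40 in Zeb2-KO replicate 2, the array with the widest (2.40).

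Among genes of the sorting gate and of stem cell identity, Slamf1, which encodes the SLAM antigen CD150, stood at 8.54 ± 0.41 against 7.24 ± 1.28 (difference 1.30, adjusted p = 0.673), and WT replicate 1 was the lowest array at 5.76. That array also correlated least with the others (mean correlation 0.841, against 0.886 to 0.908 for the rest). Its B lymphoid list mean (7.70) was the highest and its stem cell identity mean (7.88) the lowest of all arrays. Cd48, the SLAM antigen usually absent from stem cells, lay at -1.02 (adjusted p = 0.656) and Kit at 0.53. Without WT replicate 1 Slamf1 lay at 0.56 and Kit at 0.21, and without Zeb2-KO replicate 3 Cd48 lay at -0.65. The stem cell identity list had a median of 0.23, with 12 of 19 members higher, and was not called (adjusted p = 0.0845). It was called without WT replicate 3 (0.29, adjusted p = 0.0456). Its median was 0.079 without WT replicate 1, 0.37 without Zeb2-KO replicate 3 or WT replicate 2, 0.048 with quantile normalization and 0.13 with the array spread as a covariate, none called. Its members with the smallest p were Mllt3 (0.86) and Trpc6 (1.01), and Gata2 lay at 0.35 and Angpt1 at 0.23 (0.040 without WT replicate 1). The 7 lower members included Procr (-0.45), Hoxb4 (-0.38), Mecom (-0.38), Fgd5 (-0.29) and Hlf (-0.21). No member of the stem cell identity list, higher or lower, passed adjusted over the list alone. The list of multipotent and primed progenitors had a median of -0.45, with 7 of 11 lower, and was not called (adjusted p = 0.0845). It was called without WT replicate 1 (-0.42, adjusted p = 0.0253) and without Zeb2-KO replicate 3 (-0.44, adjusted p = 0.0496). Its median was -0.29 without Zeb2-KO replicate 2 and -0.24 with the array spread as a covariate, not called in either. In it Flt3 lay at 0.69, Cd34 at -0.69 and Satb1 at -0.51. Without Zeb2-KO replicate 1 Flt3 lay at 1.05 and Cd34 at -0.20.

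The stromal and endothelial list, which does not hold Fap, lay lower, with a median of -0.33 and 11 of 12 members lower (camera adjusted p = 0.0294, adjusted p = 0.583 with an estimated correlation). Among them were the matrix genes Sparc (-0.99) and Dcn (-0.60), which lay at -0.54 and -0.38 without WT replicate 3. The list call was lost with quantile normalization (median -0.19, adjusted p = 0.131), with the array spread as a covariate (-0.039, adjusted p = 0.558), and without Zeb2-KO replicate 2 (-0.23, adjusted p = 0.0685), Zeb2-KO replicate 3 (-0.21, adjusted p = 0.130), WT replicate 2 (-0.41, adjusted p = 0.0506) or WT replicate 3 (-0.37, adjusted p = 0.0544), and without Zeb2-KO replicate 1 the median was -0.51. The list of epithelial-mesenchymal transition and adhesion was not called (median 0.26, 10 of 19 higher, adjusted p = 0.10), but it was without Zeb2-KO replicate 2 (0.12, adjusted p = 0.0264). Its median was 0.054 without WT replicate 1, 0.071 with quantile normalization and 0.11 with the array spread as a covariate, none called. In it Krt18, an epithelial keratin, lay at 1.22, the tight junction gene Tjp1 at 1.16, Itga6 at 1.10 (0.65 without WT replicate 3) and Ctnnb1 at 0.98. Zeb1 lay at 0.44 (-0.082 without WT replicate 1) and Itgb1 at 0.26 (-0.030 without Zeb2-KO replicate 2). Genes of TGF-beta and BMP signalling had a median of -0.15 (adjusted p = 0.815), with Skil at 0.76 and Id3 at -0.56.

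Cytokine and growth factor receptors had a median of -0.14 and were not called (adjusted p = 0.978). Il18r1, a subunit of the interleukin-18 receptor, was the 1 member past the threshold adjusted over the list alone, at 7.32 ± 0.26 against 5.62 ± 0.16 (difference 1.70, adjusted p = 0.227 over all probe sets). Il10ra lay at -1.24 (-0.77 without WT replicate 1) and Il4ra at -0.77. Il6st lay at 0.39 and Cxcr4 at -0.28 (0.19 and -0.094 without Zeb2-KO replicate 2). The interferon response list had a median of 0.018 (adjusted p = 0.815), and 2 members passed adjusted over the list alone, both lower, namely Ifi27l2a (-1.21) and Ifit3 (-1.11). JAK-STAT genes (median -0.026, adjusted p = 0.815), p53 targets and cell cycle inhibitors (0.10, adjusted p = 0.757) and immediate early genes (0.13, adjusted p = 0.122) were not called, with Jak2 at 0.93 (0.49 without Zeb2-KO replicate 2), Gadd45a at 0.86 and Atf3 at 0.93. The immediate early list was called without Zeb2-KO replicate 2 (0.23, adjusted p = 0.0328) and with array weights (0.29, adjusted p = 0.0485). Nor were granulocyte genes (median -0.060, mean 0.10, adjusted p = 0.815), where Mpo lay at 0.88, Elane at -0.16, S100a8 at -0.15 and S100a9 at 1.42 with 10.16 in Zeb2-KO replicate 1 and 6.42 to 7.57 in the other arrays. Without Zeb2-KO replicate 1 S100a9 lay at 0.42, and without Zeb2-KO replicate 2 Elane lay at -0.032 and S100a8 at 0.0064. T and NK cell genes (median -0.17, adjusted p = 0.527) and mast cell, basophil and eosinophil genes (-0.34, adjusted p = 0.306) were not called, and Spi1, a myeloid transcription factor, lay at 0.23 (0.0057 without Zeb2-KO replicate 1). With 1 array left out the medians ran from -0.33 to -0.010 for T and NK cells, from -0.47 to -0.19 for mast cells, basophils and eosinophils, from -0.15 to 0.093 for granulocytes and from -0.17 to 0.012 for cytokine receptors, none called. They ran from -0.15 to 0.11 for the interferon response, from -0.24 to 0.036 for JAK-STAT genes, from 0.00058 to 0.30 for the p53 list and from -0.17 to -0.045 for TGF-beta and BMP signalling, none called. The immediate early median ran from 0.064 to 0.29. With the array spread as a covariate the medians were 0.080 for T and NK cells (9 of 12 higher, against 5 of 12 without it), 0.11 for granulocytes and -0.10 for the interferon response, none called. They were -0.24 for JAK-STAT genes, -0.034 for cytokine receptors, -0.044 for mast cells, basophils and eosinophils, -0.052 for TGF-beta and BMP signalling, 0.0047 for the p53 list and 0.14 for immediate early genes, none called.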

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

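The tests of single exchanged arrays, of the neighbours with Zeb2os and Fap counted, of mature B cells, of platelets, of quantile normalization and of the array spread for the gene lists were chosen after the results were seen.

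Among the 5610 probe sets of the control block, which the comparison leaves out, 1 passed an adjusted p of 0.05 in a limma fit of all 20220 probe sets, probe set 10339886, higher in all 3 arrays labelled Zeb2-KO by 3.97 (log2), and it was singled out because these probe sets were not expected to carry a difference. In that fit 461 of the block (8.22%) and 651 of the 14610 tested probe sets (4.46%) lay below an unadjusted p of 0.05, where 5% is the chance share. Fitted apart, 284 of the block (5.06%) and 1025 of the tested probe sets (7.02%) did, so which share is larger depends on the fit. Other probe sets of the block also differed without overlap between the groups but did not pass. Probe set 10338377 lay at 4.001, 10344432 at 2.98 and 10343024 at 2.512, while 10340199 lay lower, at -3.598. Differences as large as that of Fap (3.256) thus occur in the block, so size alone does not set Fap apart. In the fit of all probe sets Fap still passed (limma adjusted p = 0.03573).

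Fap and the unnamed probe set 10470911 were higher in 3 of 3 arrays labelled Zeb2-KO, by 3.26 and 4.55 (log2). Donor-strain chromosome carried along with the floxed allele could change genes near Zeb2, and Fap lies 32 measured genes away on chromosome 2 (gene order of GRCm38.p6). Of the 198 measured genes nearest to Zeb2, with Zeb2, Zeb2os and Fap left out as had been set before the test, 2 (Arhgap15 and Agps, 1.01%) lay below an unadjusted p of 0.01 against 1.53% of the genes elsewhere (Fisher's exact p = 0.772), and 77.2% of equally long runs elsewhere held as many. With Zeb2os and Fap counted it was 4 of 200 (2%, Fisher's exact p = 0.553, 34.2% of runs with as many), so neither count stands out. Only genes with a symbol were put in gene order, so the unnamed probe set 10470911 is in neither count. Its distance from Zeb2 was not examined. A strain variant in the segment or in Fap alone therefore stays open. The real grouping called 2 probe sets and the highest of the other splits of the 6 arrays 11. That makes 2 of 10 splits with as many, too few splits for a share under 0.05. The other split sets Zeb2-KO replicate 1 and WT replicates 1 and 3, the 3 arrays with the narrowest spread, against the rest. It follows the spread of the arrays, and its calls do not test Fap. With the spread as a covariate Fap stood at 3.08 (SE 0.23), against 3.26 (SE 0.28) without it. Fap lost its call in that fit, which has 3 residual degrees of freedom, and the unnamed probe set kept its own. The lost call therefore does not show that the spread accounts for Fap. An effect of Zeb2 loss on Fap, which the design names, also stays open and untested.

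Zeb2 was higher in the arrays labelled Zeb2-KO, by 1.48 (log2). An exchange of 1 array of each group cannot be decided from Zeb2. Of the 9 such exchanges, 7 leave its difference above 0 and 2 turn it below 0. These 2 differences are -0.22 (SE 0.58) and -0.10 (SE 0.56), both smaller than their SE, so no exchange makes Zeb2 clearly lower. More monocytes or dendritic cells, which express Zeb2, in the sorts labelled Zeb2-KO should raise their list. Its median was -0.37, with 17 of 19 members lower, and -0.065 with the array spread as a covariate, with 11 of 19 lower. Neither value shows a rise. The fall itself is weak evidence, since 4 genes of the list are also counted as mature B cell genes below. The array spread stays open, since with it as a covariate the difference was 0.77 (SE 0.30), and so does an exchange of all labels, under which 1.48 would only change sign and which no value here can exclude. A raised signal from a deleted allele outside the removed part, the biological possibility, stays open because the labels do not say which part that is.

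The megakaryocyte and erythroid lists lay higher and the B lymphoid and monocyte lists lower. After quantile normalization, which gives all arrays 1 distribution, all 4 lists were still called and kept at least 0.774 of their medians, which argues against unequal width of the distributions as the whole cause. With the array spread as a covariate at most 0.290 of the median remained in the B lymphoid and monocyte lists and up to 0.733 in the megakaryocyte and erythroid lists, so an array property that goes with the spread may contribute to the former and stays open for the latter. Other cells may contribute, although the sort on lineage markers, Kit and Sca-1 is meant to remove mature B cells and platelets. In WT the B lymphoid genes Cd79b (8.80), Pax5 (8.35) and Ms4a1 (8.01) lay above the median mean of all tested probe sets (log2 6.63). Others, such as Ighm (6.35) and Blk (6.18), lay below it. The gate alone therefore does not exclude carried-over cells. The median difference between the groups was -0.66 over 13 genes counted as mature B cell genes. It was -0.30 over 6 counted as early B precursor genes (gap -0.36, permutation p over genes 0.0446, genes not being independent). These sets are not specific to their cells. Of the 13 genes, 4 are also in the monocyte list and 8 lay above the median level in both groups. Cd74 stood at 8.59 in the arrays labelled Zeb2-KO and 9.57 in WT, and H2-Ab1 at 9.46 and 10.09. Erg, among the 6, is also in the stem cell identity list. The gap therefore does not cleanly set mature against early B cells. The 10 abundant platelet transcripts had a median of 0.84, with 7 at 0.5 or more but Gp9 at -0.094. The real grouping called 7 lists and the highest of the other splits, again the one that follows the array spread, also 7, which makes 2 of 10, too few for a share under 0.05, and a shift of lineage genes with Zeb2 loss stays open and untested.

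The real grouping gave 228 probe sets at an unadjusted p under 0.01 and 1.5-fold and the highest of the other splits, the one that follows the array spread, 693, so that 2 of 10 splits gave as many, too few splits for a share under 0.05.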

How the results depend on the processing

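The array-spread covariate, the control block included and the arrays with Y-linked signal left out together were chosen after seeing the data. The cause of a change was not tested except where fewer probe sets or arrays were used. Centring, trended or robust variance priors and the control block included (3 calls) kept the counts of calls, of descriptive changes and of lists within 1.5 times, and these and the mean of all probe sets of a gene, run for the lists only, kept the 7 lists called. Zeb2 has 1 probe set, so its mean over probe sets gave no value.

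The number past an adjusted p of 0.05 (2 as reported) was 1 with only probe sets at or above the median mean, with 1 probe set per gene, with the array-spread covariate and without the arrays with Y-linked signal, and 978 with array weights. The number at an unadjusted p under 0.01 and 1.5-fold (228) was 110 with the dim filter, 1864 with array weights and 137 with the covariate, and the share higher (86.4%) was 71.0% with array weights and 51.1% with the covariate. Zeb2 with array weights was 1.67. The number of lists called (7) was 4 with the dim filter, 3 with the covariate and 0 with an estimated correlation or fry. The dim filter left the erythroid and stromal lists with too few members to test, while oxidative phosphorylation was tested there and not called.

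With an estimated correlation and with fry, medians are those reported (megakaryocyte 0.75, erythroid 0.76, B lymphoid -0.59, monocyte -0.37, cell cycle 0.48, stromal -0.33, oxidative phosphorylation 0.27), and fry's adjusted p was 0.192, 0.192, 0.324, 0.326, 0.371, 0.363 and 0.623 in that order. Oxidative phosphorylation was 0.27 with the dim filter (not called), 0.057 with quantile normalization (not called) and reversed to -0.17 with the covariate, where it was called as lower. With the covariate monocyte was -0.065, B lymphoid -0.17, cell cycle 0.036 and stromal -0.039, and these 4 were not called. Stromal was -0.19 with quantile normalization, not called.

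With the replicate block (the replicate number in the fit) 0 probe sets passed (adjusted p of Fap 0.129 and of the unnamed probe set 0.0882), 409 had an unadjusted p under 0.01 and 1.5-fold, 2595 had an unadjusted p under 0.05, and 8 lists were called, the main 7 and ribosomal protein genes (adjusted p = 0.00824). Deviations of same-numbered arrays from their group means correlated at 0.36, 0.41 and 0.047, and each array correlated best with its own number. Raised Y-linked signal marked replicate 1 of both groups. The interquartile ranges also had the same order in both groups (1.83, 2.40 and 2.11 in the arrays labelled Zeb2-KO, 1.59, 2.03 and 1.77 in WT). The labels name no pairing, so the main fit took none, but a pairing by number stays open.

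Leaving out each array in turn gave 2 to 18 probe sets past the adjusted threshold, 116 to 573 at the descriptive one, a share higher of 71.2% to 88.3% and 6 to 8 lists. List medians ran from 0.47 to 0.89 for erythroid (0.50 where it was not called), from -0.51 to -0.21 for stromal, from 0.022 to 0.43 for oxidative phosphorylation, from -0.78 to -0.33 for B lymphoid, from -0.53 to -0.24 for monocyte, from 0.56 to 0.89 for megakaryocyte and from 0.34 to 0.67 for cell cycle. Both calls remained called in each, with an adjusted p of Fap between 0.000432 and 0.0187. Of the 120 named values, 54 came to pass with array weights. Signal over background limits the dimmest probe sets, for which no detection call was used here.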

Other observations

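The probe sets of Adgrl2 and of Chd7 differed widely from each other, and both genes were looked at after their values were seen. Adgrl2 has 8 probe sets with differences from -0.20 to 3.84 (log2), 5 of them at 1 or more, and 4 without overlap between the groups. Its probe set with the largest difference, 10502780, stood at 9.75 ± 0.60 in the arrays labelled Zeb2-KO and at 5.92 ± 1.80 in WT (SD, n = 3), where the arrays gave 4.97, 7.99 and 4.79 (adjusted p = 0.286). Chd7 has 23 probe sets with differences from -2.06 to 2.20, 5 of them at -1 or below and 1 at 1 or above. Gene-level values of Adgrl2 and Chd7 therefore depend on the probe set chosen.

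The sex of the mice is not given in the labels used here, and sex-linked genes separated 1 array of each group from the others. Eif2s3y, a Y-linked gene, stood at 6.46 in Zeb2-KO replicate 1 and 5.20 in WT replicate 1, against 3.10 to 3.38 in the other 4 arrays. Kdm5d stood at 6.90 and 5.36 against 4.27 to 4.83, and Uty at 5.16 and 4.82 against 3.79 to 4.09. Xist, expressed from the inactive X chromosome, stood at 8.15 and 9.70 in the same arrays, below the 10.70 to 11.09 of the others. Both groups hold 1 such array.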
